A study of Mus musculus with 6 samples.

How the data were processed

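RNA was sequenced from the nuclear fraction of mouse neural precursor cells grown from the dorsal forebrain of embryos at embryonic day 13.5, at passage 6 to 7, with EGF and FGF2 at 20 ng/ml each, and harvested near 80% confluency. There were 6 samples, 3 labelled wild type (WT lines 3, 8 and 19) and 3 labelled Fmr1 knockout (KO lines 3, 13 and 16). Per the series' design text, the 3 lines of a genotype were independent. Per the labels' protocols, nuclei were separated with a commercial extraction kit, RNA was purified with TRIzol, and a preparation was kept when RT-qPCR gave a high U1 and a low beta-actin signal.

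The authors deposited raw counts per gene symbol, with 23337 gene rows for each sample and no normalization. Per the submitters' processing notes, the tools included cutadapt 1.14, STAR, HTSeq 0.7.2 and DESeq2, and the genome build was mm10. The annotation, the strand setting of the library kit and of the counting, and the role of each tool are not given in the sources used here, so reads from genes on opposite strands of the same bases cannot be told apart. Per the file headers, each file holds a gene symbol and a single column of counts. Total counts ran from 18702738 to 26789522 per sample, so that 1 count was worth 0.0373 to 0.0535 CPM (counts scaled to the library total in the usual way), and 3 counts, taken as the floor for a gene without counts, were worth 0.112 to 0.16 CPM. Intervals and floors cover counting error only. The rows held 0 mitochondrially encoded genes, so a planned share of mitochondrial counts could not be computed.

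Gene symbols were matched to a RefSeq gene table of the same mouse assembly (GRCm38), 21158 directly and 1918 through a synonym, with 261 left unmatched. Positions, lengths and overlapping exons were taken from GENCODE mouse release 21, which held 22795 of the symbols. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes passed filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and genotype was tested in a quasi-likelihood fit with robust dispersion over the 6 samples, with 4 residual degrees of freedom before the pooling of spread across genes. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The standard error (SE) of a log2 fold change was derived from its F statistic. Values in CPM are on the TMM scale for single genes, while shares of counts, Xist and Y-linked levels are over the total counts of the library. Log2 CPM for the principal components carried a prior count of 2.

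Before the data were examined, 48 gene lists were written down: pathways, markers of neural and other cell types, and lists that reflect RNA quality. Lists with at least 5 tested members, 44 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry beside it. Microglial, erythroid, posterior Hox and mitochondrial lists had fewer tested members and were only described. Counts of members past the threshold are over all genes tested, and also, where stated, adjusted over the list alone. Another 8 lists were written after the data were seen and are described without a test. The genes named were fixed by a rule set before the data were examined: Fmr1, then the 12 highest and the 12 lowest fold changes among called genes whose KO and WT values did not overlap and whose mean was at least 1 CPM in the higher group, leaving out symbols of predicted or unnamed genes, then up to 4 members of each list described by smallest p-value. Where a count of 5 or fewer list members is named outside that rule, the text says so. Some genes that met the rule are not reported here. Shares of counts were compared with an exact permutation test, two-sided.

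The statistics were tested on simulated data with the means and depths of these libraries. For the KO against WT comparison, 200 of 13925 simulated genes were changed: 25.4% of those changed 1.5-fold were called, 82.1% of those changed 2-fold and 97% of those changed 4-fold. Of the simulated calls, 11.7% were false, above the nominal threshold. A list of raised genes was called, and 0 of 40 unchanged lists were. The simulated genes were drawn independently of one another, so these lists cannot show how often camera calls an unchanged list of correlated genes. In the real data the estimated correlation was 0.44 for cholesterol genes, 0.67 for oxidative phosphorylation genes and 0.79 for ribosomal protein genes.

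Alternatives fixed before the data were examined were other size factors (those of DESeq2 1.42.0, upper-quartile, library size alone), no filter on low counts or a filter of 1 CPM in 3 libraries, limma-voom without and with sample weights, the DESeq2 Wald test, a threshold of 0.10, leaving out ribosomal protein, histone and small RNA genes, a covariate from Y-linked genes, and leaving out each sample in turn. Chosen after seeing the data were a covariate for Xist state (at least 1000 CPM), removal of smooth trends with GC content and exonic length (98.6% of tested genes had both values), a test against a 1.5-fold change, WT line 19 and KO line 3 left out together, and nuclear-retained RNAs counted without Xist. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.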

Results

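Nuclear RNA was compared between neural precursor cell lines of 2 genotypes, WT and Fmr1 knockout, to ask how the RNA content of the nucleus differs when Fmr1, the gene of the RNA-binding protein FMRP, is disrupted. Each genotype had 3 lines. Total counts were 26789522, 19578649 and 18702738 for WT lines 3, 8 and 19, and 19520481, 23324162 and 23040400 for KO lines 3, 13 and 16. Between 16633 and 17248 genes had a count in a library, and 13925 genes had enough counts to be tested. Every pair of replicates of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 10.8 between WT lines 3 and 8 and 16.4 between KO lines 13 and 16. WT line 19 stood further apart, at 61.3 and 62.8 from the other WT lines, and so did KO line 3, at 72.6 and 91.5 from the other libraries labelled KO. By this measure KO line 3 was about as far from WT line 8 (90.0) as from KO line 16. Abundant genes weigh heavily in this measure. Xist, the X-inactivation RNA, held 383749 counts in KO line 3 and 363810 in WT line 8, against 39 in KO line 16. The near tie thus partly reflects Xist, which also sets WT line 19 (1508 counts) apart from the other WT lines. By Spearman's rho KO line 3 was nearer KO line 16 (0.982) than WT line 8 (0.973). WT line 19 also held more of the ribosomal RNA precursor Rn45s, at 18477 CPM against 1033 to 2597 CPM in the other 5 libraries.

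The targeted gene did not follow the labels in every library. Fmr1 (ENSMUSG00000000838.17, chromosome X, 68678541 to 68717963 in GRCm38) measured 256 ± 28.1 CPM in WT (SD, n = 3) and 238 ± 117 CPM in the libraries labelled KO (SD, n = 3), and its log2 fold change of -0.10 (SE 0.29) did not pass edgeR's quasi-likelihood test (adjusted p = 0.795 after Benjamini-Hochberg adjustment). KO lines 13 and 16, at 188.2 and 153 CPM, lay below the WT range of 223 to 274 CPM, while the library labelled KO line 3 lay above it at 371 CPM. Without KO line 3 the log2 fold change was -0.58 (adjusted p = 0.00152). It turned positive without KO line 13 (0.04), without KO line 16 (0.14) and with GC and length trends removed (0.07), in each case short of the threshold. Counts per gene do not show which exons were read, so they do not show whether the remaining Fmr1 RNA is intact. Since Fmr1 goes against the label of KO line 3, the directions below are between libraries labelled KO and libraries labelled WT.

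The lines also differed in X- and Y-linked RNA within each genotype. Xist, the RNA that coats the inactive X chromosome, was at 15783 CPM in WT line 3, 18582 CPM in WT line 8 and 19659 CPM in KO line 3, against 80.6 CPM in WT line 19, 3.39 CPM in KO line 13 and 1.69 CPM in KO line 16. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 710 CPM in WT line 19, 429 CPM in KO line 13 and 362 CPM in KO line 16, and to 33.7, 10.2 and 0.666 CPM in WT line 3, WT line 8 and KO line 3. Both genotypes thus held Xist-high and Xist-low lines, with 2 Xist-high lines in WT and 1 among the libraries labelled KO, and the adjusted p of these 5 genes in the edgeR test between genotypes ran from 0.802 to 0.986.

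**Figure D1:**
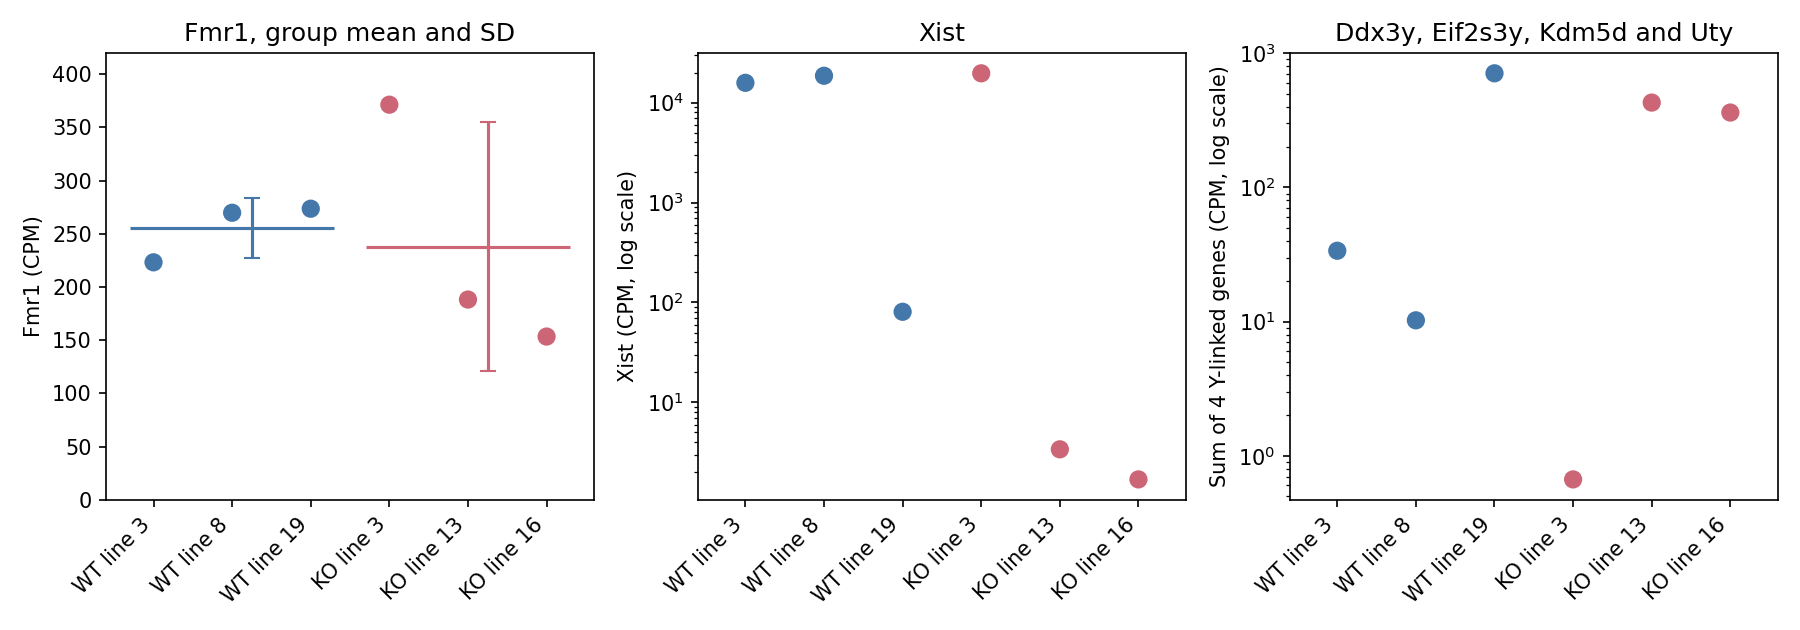
Fmr1 (CPM, linear axis, with the mean and SD of each group of 3 lines), Xist and the sum of 4 Y-linked genes (CPM, log axes) in each library, WT in blue and libraries labelled KO in red. Fmr1 ranged from 153 CPM in KO line 16 to 371 CPM in KO line 3, and Xist was at 15783 CPM or more in WT lines 3 and 8 and in KO line 3.

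The libraries labelled KO had a nuclear RNA profile clearly apart from that of WT. At its preset correlation camera called gene lists of cholesterol synthesis, Hedgehog signalling, the oligodendrocyte lineage and the G1/S phase higher in the libraries labelled KO. Lists of astrocyte markers, oxidative phosphorylation genes and heat shock genes were called lower. With an estimated correlation these calls were lost (adjusted p from 0.515 to 0.764), and without KO line 3 the heat shock call was lost too (adjusted p = 0.0506). Single genes differed by large factors: Igf2bp1, which encodes an RNA-binding protein of the fetal brain, was at 84.6 ± 7.82 CPM in the libraries labelled KO and 2.83 ± 0.673 CPM in WT, and Gria1, an AMPA receptor subunit, was at 11.3 ± 1.80 CPM against 236 ± 40.3 CPM (SD, n = 3 each). The edgeR quasi-likelihood test called 5884 of 13925 genes (42.2%) after Benjamini-Hochberg adjustment, 3040 higher and 2844 lower in the libraries labelled KO. Of the called genes, 796 were at least 2-fold higher and 1174 at least 2-fold lower, and 221 were at least 4-fold higher and 317 at least 4-fold lower. The KO and WT values did not overlap in 54.3% of the tested genes, where a random order of the 6 libraries would give 10% per gene. Genes move together, so line differences that happen to follow the labels could exceed that 10% too. The first principal component held 74.7% of the variance and separated the genotypes, while the second, with 13.7%, set KO line 3 apart from the other libraries labelled KO. Without WT line 3 the number of genes called higher was 1994, and no other left-out library moved that number or the total by more than 1.5 times.

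**Figure D2:**
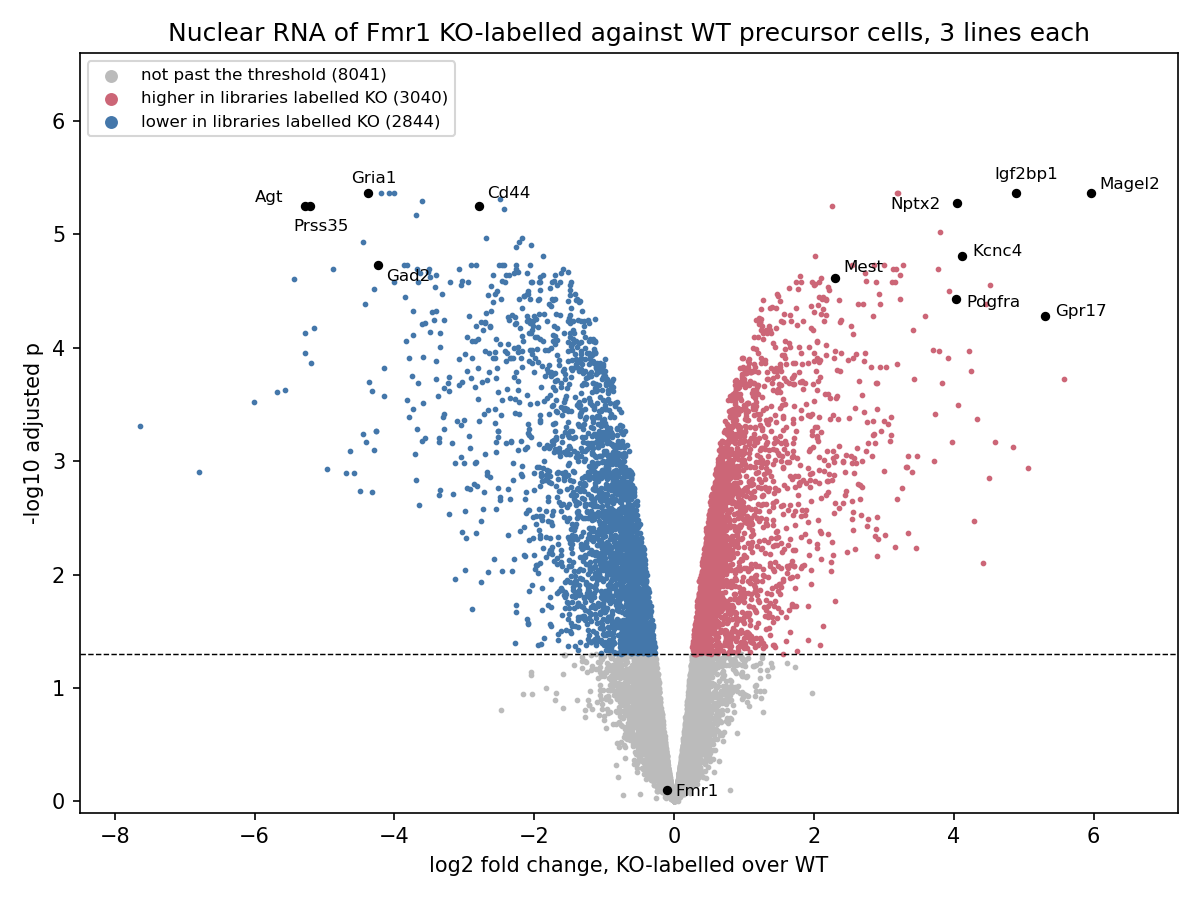
Log2 fold change of each tested gene between libraries labelled KO and WT (x axis) against -log10 of the adjusted p-value of edgeR's quasi-likelihood test (y axis), with 3 lines per group and the threshold of 0.05 as a dashed line. Red points are the 3040 genes called higher, blue points the 2844 called lower, and Fmr1 lies near 0 below the threshold.

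Among the 12 highest genes, Magel2, an imprinted gene of the Prader-Willi region (chromosome 7, 62377010 to 62381640 in GRCm38), was at 14.7 ± 1.92 CPM in the libraries labelled KO and 0.231 ± 0.0357 CPM in WT, a log2 fold change of 5.96 (SE 0.23, edgeR adjusted p = 4.34e-06). Gpr17, a receptor of oligodendrocyte precursors, followed at a log2 fold change of 5.30 (SE 0.44) and Igf2bp1 at 4.89 (SE 0.18). The exons of Gpr17 overlap those of Lims2. Dcx, a microtubule-binding protein of migrating neurons, was higher by a log2 fold change of 4.06 (SE 0.49), and Nptx2, a secreted synaptic protein, by 4.05 (SE 0.18). Cbln1, a secreted organiser of synapses, had a log2 fold change of 4.52 (SE 0.32), Cnih3, an AMPA receptor auxiliary subunit, of 4.25 (SE 0.44), and Dscaml1, a cell adhesion molecule, of 4.22 (SE 0.40). The potassium channel gene Kcnc4 rose from 2.19 ± 0.879 to 37.9 ± 1.63 CPM. Tox and AW551984 had only 3 counts each over the WT libraries, so their ratios of 22.1 and 21.1 carried 95% counting intervals of 7.23 to 110 and 6.89 to 105.

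Among the 12 lowest genes, Ptger2, a prostaglandin E2 receptor, had no counts in the libraries labelled KO and 1.12 ± 0.279 CPM in WT, which makes it at least 24.5-fold lower against a floor of 3 counts over those libraries together. Agt, the precursor of angiotensin and a product of astrocytes (chromosome 8, 124556534 to 124569706 in GRCm38), was at 0.26 ± 0.0873 CPM in the libraries labelled KO and 10.3 ± 0.803 CPM in WT, a log2 fold change of -5.28 (SE 0.25, edgeR adjusted p = 5.60e-06). Prss35, a serine protease-like protein, fell from 42.4 to 1.12 CPM, Ppl, a desmosome-associated plakin, from 59.9 to 1.98 CPM, and Gstt3, a glutathione S-transferase, from 35.9 to 0.988 CPM. Met, the receptor of hepatocyte growth factor, had a log2 fold change of -4.46 (SE 0.24), Tfap2c, a transcription factor, of -4.42 (SE 0.34), Bcl3, a co-regulator of NF-kappaB, of -5.20 (SE 0.53), Chodl of -5.27 (SE 0.47) and the potassium channel gene Kcnk9 of -4.70 (SE 0.74). Gbp8 and Vdr, the vitamin D receptor gene, had 3 counts each over the libraries labelled KO, so their ratios of WT over KO of 54.7 and 35.1 carried 95% counting intervals of 18.4 to 268 and 11.7 to 173. The exons of Gbp8 overlap those of Gbp4 and Gbp9, so reads of these 3 genes may be shared.

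**Figure D3:**
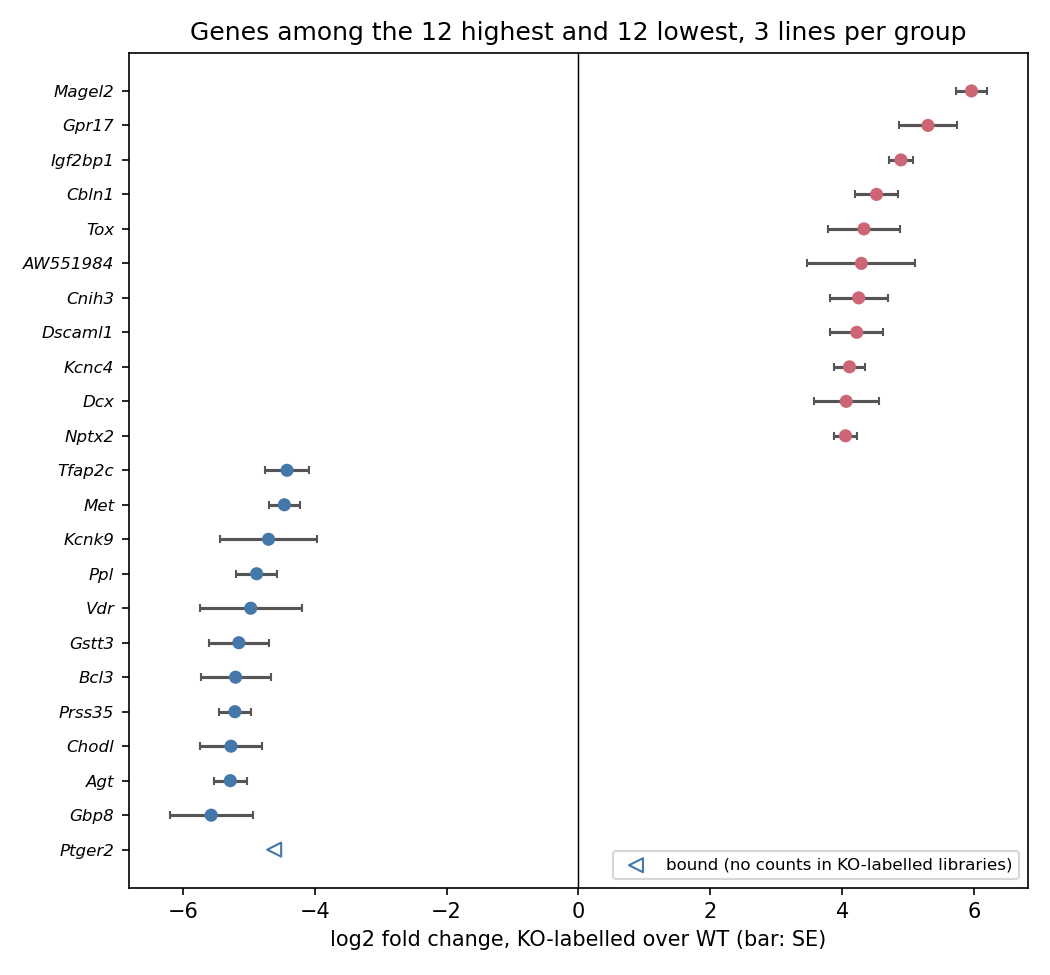
Log2 fold change (x axis) with its SE (bars) for genes among the 12 highest and the 12 lowest between 3 libraries labelled KO and 3 WT libraries. Magel2 is the highest at 5.96, and Ptger2, drawn as an open triangle, is a bound since the libraries labelled KO held no counts.

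Of the 44 gene lists tested, camera called 9 at the preset correlation, 6 higher and 3 lower in the libraries labelled KO, fry called 15, and camera with an estimated correlation called 0, with 2 at an unadjusted p under 0.05 (oligodendrocyte and astrocyte markers). Of the 10 splits of the 6 libraries into 3 and 3, 7, the real one included, had at least as many lists past camera at the preset correlation. The counts of called members below stand beside 42.2% called over all tested genes. Members called in either direction made up less than that in the G2/M, ribosomal protein, radial glia, m6A, RNA export and splicing lists, among others. Of 25 tested genes of cholesterol biosynthesis, 20 rose in the libraries labelled KO, 0 fell and 5 did not pass, with the same 20 and 0 adjusted over the list alone (camera adjusted p = 5.80e-06, and adjusted p = 0.764 with an estimated correlation). Lss, which makes lanosterol, rose from 56.6 ± 10.5 to 165 ± 14.1 CPM (log2 fold change 1.54, SE 0.15). Fdps, Acat2 and Mvk, which act earlier in the pathway, rose by log2 fold changes of 1.38, 1.43 and 1.33.

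In the Hedgehog pathway list, 13 of 19 genes rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 5.20e-05, and adjusted p = 0.764 with an estimated correlation). The target gene and receptor Ptch1 rose by a log2 fold change of 1.07 (SE 0.11), and the transcription factors Gli1 and Gli3 by 2.23 (SE 0.26) and 1.41 (SE 0.11). The gene that fell, Iqce, had a log2 fold change of -0.32 and was named after its value was seen. Exons of Gli1 overlap those of Arhgap9.

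Oligodendrocyte lineage markers rose in 9 of 14 tested genes, and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 2.59e-04, and adjusted p = 0.515 with an estimated correlation). Pdgfra, the growth factor receptor of oligodendrocyte precursors, rose from 2.31 ± 1.24 to 39 ± 1.46 CPM (log2 fold change 4.03, SE 0.30), Sox10 from 0.469 to 3.26 CPM, and Olig2, which is also in the radial glia list, from 349 to 694 CPM. The member that fell, Cnp, had a log2 fold change of -0.47 and was named after its value was seen. Astrocyte markers moved the other way: of 19 tested, 9 fell and 1 rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 2.30e-05, and adjusted p = 0.53 with an estimated correlation). Beside Agt, the adhesion receptor Cd44 fell from 228 ± 33.3 to 32.9 ± 0.51 CPM, the secreted chaperone Clu from 99.8 ± 12.5 to 7.75 ± 2.50 CPM, and the gap junction gene Gja1 from 85.9 ± 4.26 to 32.8 ± 2.21 CPM. The astrocyte marker that rose, Fgfr3, had a log2 fold change of 1.44 and was named after its value was seen. Neural stem cell and radial glia markers, the class nearest to the cultured cells, passed in 6 of 24 genes, 3 higher and 3 lower, or 3 and 0 adjusted over the list alone. Nr2e1 (log2 fold change 0.64) and Olig2 (0.99) were among those that rose, and Slc1a3 (-0.35), Vim (-0.48) and Ptprz1 (-0.39) fell, the last 2 named after their values were seen (camera adjusted p = 0.327). The call of Slc1a3 was lost when any library other than KO line 3 was left out.

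In the G1/S list, 26 of 42 genes rose and 1 fell, or 29 and 1 adjusted over the list alone (camera adjusted p = 5.20e-05, and adjusted p = 0.764 with an estimated correlation). Chaf1b, a chromatin assembly factor, Rrm2, a ribonucleotide reductase subunit, Clspn and Fen1, which act in DNA replication, rose by log2 fold changes of 0.84, 0.90, 0.64 and 0.75. The member that fell was Brip1, at -0.68, named after its value was seen. In the G2/M list 15 of 52 genes rose, among them Tacc3 (log2 fold change 1.06), Ncapd2 (0.81), Aurkb (0.80) and Gtse1 (0.63), and 3 fell, Cenpf, Hmmr and Anln, at -0.47, -0.73 and -0.64, named after their values were seen. The G2/M call (camera adjusted p = 0.0467, and adjusted p = 0.879 with an estimated correlation) ended without KO line 3 (adjusted p = 0.40), without WT line 19 (adjusted p = 0.102) and without WT line 3 (adjusted p = 0.0509). It was also lost in limma-voom with sample weights (adjusted p = 0.137), with the Y-linked covariate (adjusted p = 0.379), in fry (adjusted p = 0.157) and without WT line 19 and KO line 3 together (adjusted p = 0.621).

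Nuclear-encoded oxidative phosphorylation genes fell in 33 of 72 tested members and rose in 0, or 37 and 0 adjusted over the list alone (camera adjusted p = 5.20e-05, and adjusted p = 0.764 with an estimated correlation). Ndufa4 fell from 102 ± 20.7 to 48.5 ± 9.43 CPM and Cox6c from 68.1 to 35.9 CPM, while Cox6b2 and Ndufb4 had log2 fold changes of -1.91 and -1.18. Heat shock genes fell in 9 of 17 members and rose in 0, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.0166, and adjusted p = 0.764 with an estimated correlation). Hsp90aa1 fell from 516 ± 101 to 266 ± 24.1 CPM, and Hspa4l, Hsph1 and Hspe1 fell with log2 fold changes of -1.27, -0.70 and -0.96. Without KO line 3 the heat shock call was lost (adjusted p = 0.0506), and in fry the oxidative phosphorylation call was lost (adjusted p = 0.106). Cytoplasmic ribosomal protein genes rose in 15 of 77 members, such as Rpl10a (log2 fold change 0.61) and Rps20 (0.64), and fell in 2, Rpl39 and Rps27l, at -0.63 and -0.65, named after their values were seen. Adjusted over the list alone, 0 rose and 0 fell, and the camera call (adjusted p = 0.0275, and adjusted p = 0.879 with an estimated correlation) was lost without WT line 19 (adjusted p = 0.181), without KO line 16 (adjusted p = 0.228) and in fry (adjusted p = 0.292).

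**Figure D4:**
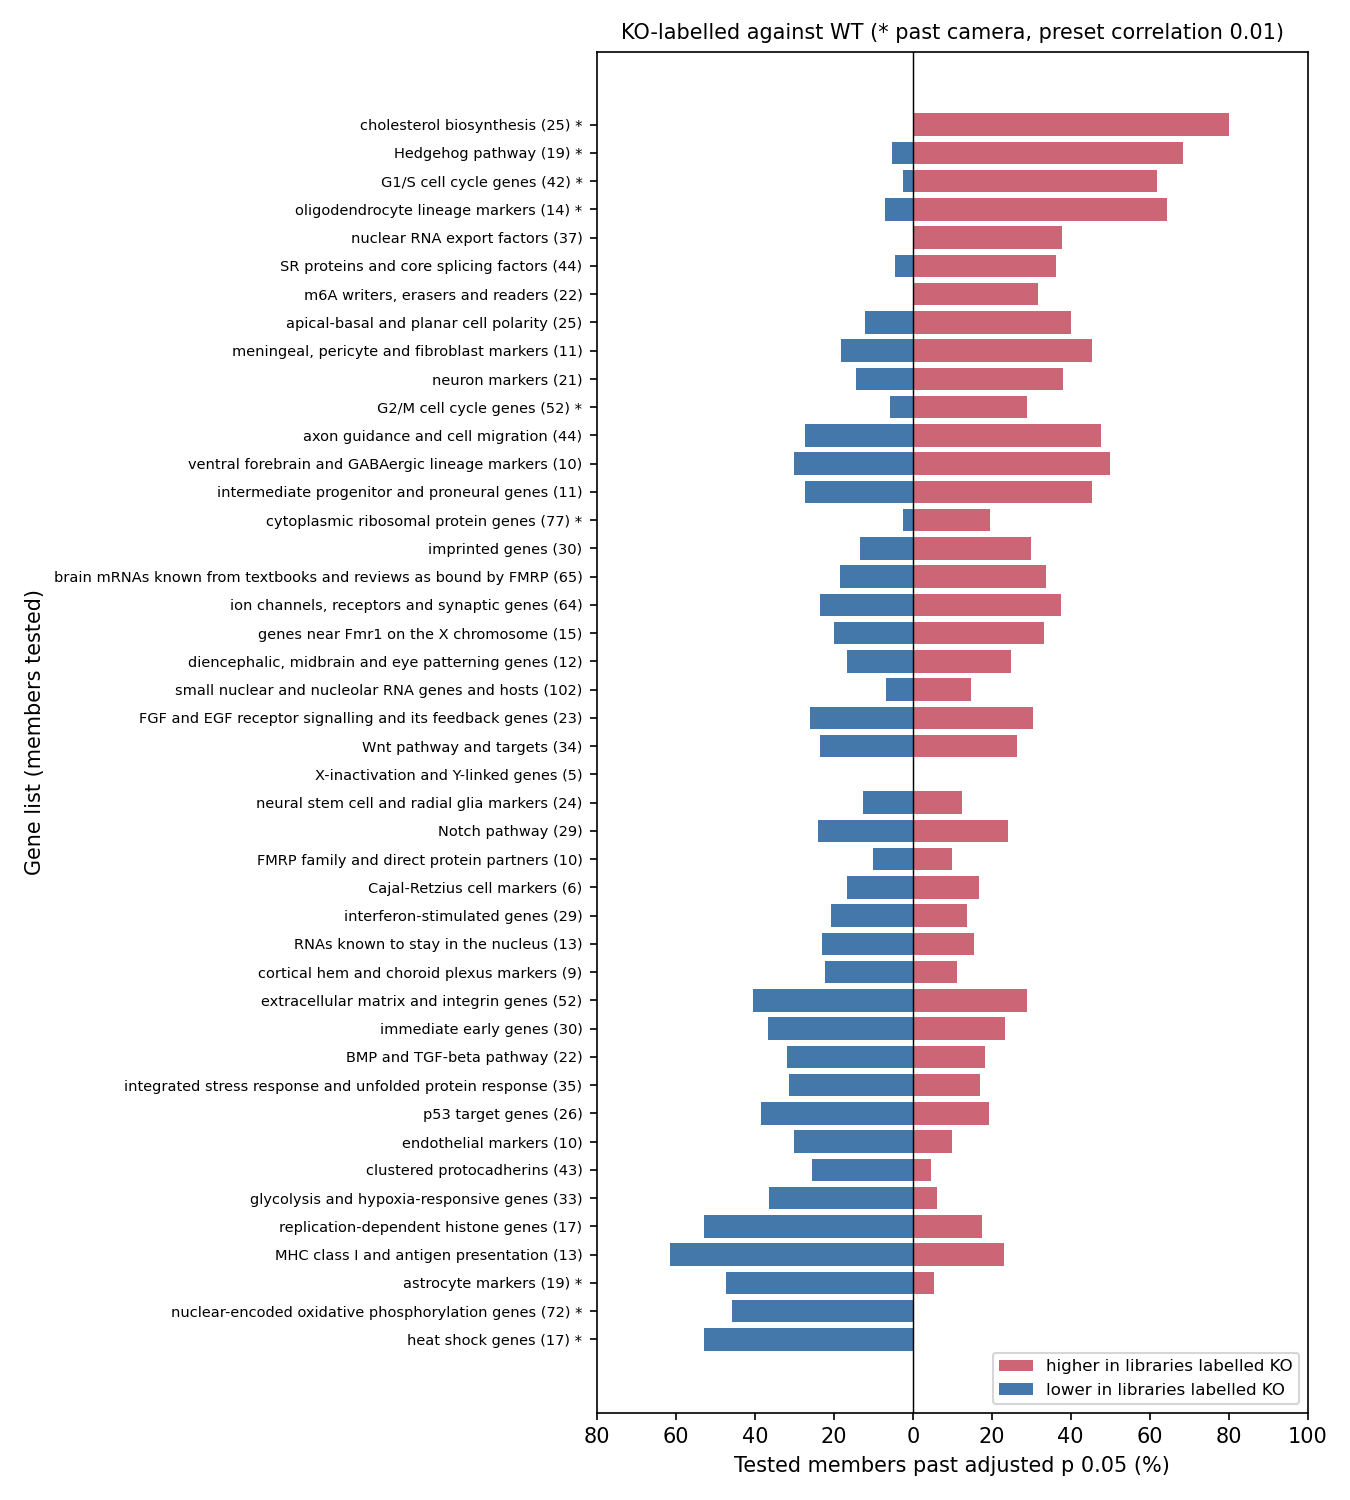
Share of the tested members of each of the 44 gene lists called higher (red, to the right) and lower (blue, to the left) in libraries labelled KO by edgeR's quasi-likelihood test, in percent, with the members tested in parentheses. A star marks the 9 lists past camera at the preset correlation of 0.01, and 0 lists passed with an estimated correlation, where 2 had an unadjusted p under 0.05.

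Brain messages known to be bound by FMRP changed in both directions. Of 65 tested, 22 rose, 12 fell and 31 did not pass, or 24 and 14 adjusted over the list alone, and the list was not called (camera adjusted p = 0.203, and adjusted p = 0.879 with an estimated correlation). Limma-voom with sample weights turned this into a call at the preset correlation (camera adjusted p = 0.047, higher). Bsn, a presynaptic scaffold, and Nlgn3, a synaptic adhesion protein, rose by log2 fold changes of 2.11 (SE 0.16) and 1.24 (SE 0.10), while Nlgn1 and App fell with -1.67 (SE 0.12) and -1.50 (SE 0.12). Of 10 genes of the FMRP family and its protein partners, Cyfip2 rose (log2 fold change 0.93, SE 0.13) and Nufip2 fell (-0.82, SE 0.29, edgeR adjusted p = 0.0495), the latter call being lost when any library but KO line 3, or the filter on low counts, was left out. Of 22 writers, erasers and readers of m6A, the methyl mark on RNA, 7 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.094). They included Igf2bp1, Zc3h13 (log2 fold change 0.60), Rbm15b (0.63) and Prrc2a (0.44), whose call was lost when any library but WT line 19 and KO line 3 was left out. Of 37 nuclear RNA export factors, 14 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 0.104), with Ddx39b, Alyref, Poldip3 and Ddx39 at log2 fold changes of 0.83, 0.71, 0.51 and 0.53. Of 44 splicing factors, 16 rose, such as Prpf8 (log2 fold change 1.08) and Srrm1 (0.85), and 2 fell, Tra2a (-0.49) and Luc7l2 (-0.78), which were named after their values were seen, with the same 16 and 2 adjusted over the list alone (camera adjusted p = 0.0904). Other tests called these lists higher. Fry called the m6A (adjusted p = 0.0261), RNA export and splicing lists (adjusted p = 0.0264 each). With GC and length trends removed, camera called RNA export and splicing (adjusted p = 0.0055 and 0.0166). With an estimated correlation none of the 3 lists was called (adjusted p = 0.764 each).

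Measures of the nuclear fraction were set side by side, since 3 libraries against 3 cannot give an exact permutation p below 0.1. Actb, the cytoplasmic control of the protocol, took 0.117 ± 0.0212% of counts in the libraries labelled KO and 0.0736 ± 0.0107% in WT (SD, n = 3 each, exact permutation p = 0.1, two-sided, the smallest possible). Ribosomal protein genes took 1.06 ± 0.21% and 0.863 ± 0.133% (SD, n = 3 each, exact permutation p = 0.4). Nuclear-retained RNAs took 1.29 ± 1.21% and 1.89 ± 0.774% (SD, n = 3 each, exact permutation p = 0.5), most of it Xist in the Xist-high lines. Without Xist they took 0.64 ± 0.182% and 0.744 ± 0.232% (SD, n = 3 each, exact permutation p = 0.6). Among these RNAs Miat and Neat1 rose by log2 fold changes of 3.17 and 0.80, and Snhg11, Airn and Tug1 fell with -0.55, -0.63 and -0.90, Tug1 being named after its value was seen. The call of Airn was lost without WT line 19 (adjusted p = 0.0627).

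Gene length showed little relation to the change between genotypes. Across 13732 genes, which are not independent replicates, Spearman's rho between the log2 fold change and genomic length was 0.012, and between the log2 fold change and GC content 0.185. The deviations of single libraries from the mean had a rho with GC content from -0.333 in WT line 8 to 0.337 in KO line 16. Of the 3433 genes of greatest genomic length, 872 rose and 734 fell, and of the 3434 shortest, 641 rose and 637 fell.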

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

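Chosen after seeing the data were the Xist covariate, the removal of GC and length trends, the test against a 1.5-fold change, WT line 19 and KO line 3 left out together, and nuclear-retained RNAs without Xist. The number of called genes (5884) stayed between 5636 and 7973 under the other scalings, filters, tools and covariates, and 94.2% to 99.3% of the main calls were shared with each of these. It dropped to 1775, with 755 higher and 1020 lower, when tested against a 1.5-fold change, which asks for larger changes. Leaving out each library gave 4262 to 7610 called genes, 1994 to 3666 higher and 2120 to 3944 lower, with the fewest higher without WT line 3 and the most calls without KO line 3. Without WT line 19 and KO line 3 together 7625 genes were called, which held 93.6% of the main calls. Fmr1 turned to a log2 fold change of 0.066 with GC and length trends removed (adjusted p = 0.714), and ranged from -0.58 without KO line 3 to 0.14 without KO line 16, with 0.04 without KO line 13. It passed the threshold with the Y-linked covariate, which singles out KO line 3 (log2 fold change -0.56, adjusted p = 0.00171), and without WT line 19 and KO line 3 together (-0.53, adjusted p = 0.00204). In that last setting Uty, at -0.48 in the main comparison, turned to 3.365 because the 2 WT lines left are Xist-high and the 2 libraries labelled KO are Xist-low. The 9 called lists numbered 7 to 13 under other scalings, filters, limma-voom, covariates, removed trends and left-out libraries, 0 with an estimated correlation and 15 with fry, which asks whether a list's genes move on balance rather than more than other genes. Lists were not run with the DESeq2 Wald test. Cholesterol, Hedgehog, oligodendrocyte, G1/S, astrocyte and oxidative phosphorylation lists kept their call in each of these but the estimated correlation, and, for oxidative phosphorylation, fry. Differences in the share of counts between libraries labelled KO and WT kept their sign in each alternative but moved with single libraries. In percent of counts, ribosomal protein genes ran from 0.0736 without KO line 16 to 0.266 without KO line 3 (0.119 without WT line 19). Nuclear-retained RNAs ran from -1.29 without KO line 3 and -1.03 without WT line 19 to -0.297 without WT line 8, -0.338 without KO line 13 and -0.166 without KO line 16, with -0.104 without Xist. Actb ran from 0.0314 without KO line 16 to 0.0515 without KO line 13. The correlation with gene length stayed within the spread of single libraries, from -0.0278 without KO line 3 to 0.0591 without KO line 16. For named genes and alternatives, 4187 comparisons stayed on the same side of the threshold, 79 lost the call (45 of them against the 1.5-fold change), 12 gained it and 1, Uty, gained it with the opposite sign. Sign changes short of the threshold, such as those of Fmr1, are not counted here. For gene lists 794 stayed, 21 lost the call and 21 gained it. The cause of the other changes was not tested. No paired analysis was possible because WT lines 3, 8 and 19 and KO lines 3, 13 and 16 share only the number 3. Genes with a few counts, such as Ptger2, are limited by depth to a bound.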

Other observations

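Chosen after the results were seen were 8 of the gene lists, the Xist covariate and the removal of trends, and the tests on the label of KO line 3, on the Fmr1 allele, on other groupings for the gene count, on cytoplasmic RNA and on the neighbourhood of Fmr1. Signalling and receptor genes outside the called lists changed in both directions in the libraries labelled KO. In the Notch pathway list, 7 of 29 genes rose and 7 fell (camera adjusted p = 0.749): the ligands Dll1 and Dll3, which are also proneural markers, rose by log2 fold changes of 1.74 (SE 0.12) and 2.84 (SE 0.23), while the ligand Jag1 and Dner fell with -1.20 (SE 0.11) and -2.17 (SE 0.17). In the Wnt list 9 of 34 rose and 8 fell (camera adjusted p = 0.548), with Wnt7b at -1.97, Fzd5 at -1.47 and Tcf7l1 at 2.17. Among 64 ion channel, receptor and synaptic genes 24 rose and 15 fell (camera adjusted p = 0.32). In a list of AMPA and kainate receptor subunits written after the data were seen, 4 of 9 rose and 3 fell. There Gria1 fell from 236 to 11.3 CPM while Gria2 rose from 144 ± 50 to 926 ± 346 CPM, and Grik3 and Grik2 rose by log2 fold changes of 3.09 and 2.27. Among imprinted genes 9 of 30 rose and 4 fell (camera adjusted p = 0.0904, 0.0274 without KO line 13, 0.764 with an estimated correlation, and adjusted p = 0.0386 with fry): Magel2, Mest (log2 fold change 2.30, with exons that overlap Copg2) and Nnat (1.99) rose, and Zim1 (-1.88), Airn (-0.63), Igf2r (-1.04) and Nap1l5 (-0.65) fell, the last 2 named after their values were seen. The list of ventral forebrain and GABAergic markers, in which 5 of 10 rose and 3 fell, held a fall of Gad2 from 112 ± 38.9 to 5.93 ± 0.856 CPM beside a rise of Gsx1 (log2 fold change 1.46). Its median of 0.22 and its mean of -0.29 differed in sign.

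Lists written after the data were seen are described without a test, since genes already seen cannot test them. Guanylate-binding proteins fell in 5 of 8 and rose in 2, with Gbp9 falling from 187 ± 6.77 to 14.5 ± 3.67 CPM, although Gbp4, Gbp8 and Gbp9 overlap in their exons. Glutathione S-transferases fell in 9 of 16 and rose in 0, while fatty acid synthesis genes rose in 10 of 17 and fell in 2, with Fasn rising from 672 ± 113 to 1765 ± 283 CPM. The lists of annexins and S100 proteins, complement components, and chromodomain and high-mobility-group proteins had median log2 fold changes of -0.31, -1.89 and 0.40, and connexins had too few tested members. In the list fixed beforehand for MHC class I and antigen presentation, 8 of 13 fell and 3 rose (camera adjusted p = 0.246, 0.764 with an estimated correlation, and adjusted p = 0.0198 with fry), with B2m at a log2 fold change of -1.05 and Nlrc5 at -2.04. The 3 that rose were H2-Q4 (1.15), H2-K1 (0.87) and H2-D1 (0.60), the last 2 named after their values were seen. The sums over the endothelial, mesenchymal and microglial lists were 31, 217 and 41.1 CPM in the libraries labelled KO and 30, 178 and 56.1 CPM in WT, against 13752 and 14647 CPM for radial glia. Those over the neuron, astrocyte and oligodendrocyte lists were 2141, 2384 and 1326 CPM in the libraries labelled KO and 1963, 3050 and 819 CPM in WT. Of 21 tested neuron markers 8 rose, such as Stmn3 (log2 fold change 2.58) and Bcl11b (1.65), and 3 fell. That list was not called by camera (adjusted p = 0.143, and 0.764 with an estimated correlation) but was called higher by fry (adjusted p = 0.0275). Of the microglial, erythroid and Hox lists 4, 1 and 2 genes could be tested. The median and the camera direction also differed in sign for nuclear-retained RNAs (median -0.06), stress response genes (0.04), hem and choroid plexus markers (0.26), diencephalic and midbrain genes (-0.27) and FGF and EGF signalling (0.01), none of them called. The Y-linked genes in WT line 3, at 33.7 CPM, were 6.75% of the mean of the Xist-low libraries.

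Fmr1 was not lower in every library labelled KO. KO line 3 lay at 44.4 on the first principal component, beside 48.4 and 48.3 for the other libraries labelled KO and -45.1 to -49.5 for WT. Its profile thus went with those libraries. That does not show its Fmr1 genotype, since line differences that happen to follow genotype would place it there too. Of the 7521 genes called without KO line 3 and tested in all libraries, it lay nearer the other lines labelled KO than WT at 68.9%. At 89.3% of them it lay on their side of the WT mean. The other libraries lay nearer their own group at 90.1% to 97%. Their gene sets were smaller (4230 to 5170 genes) and called with KO line 3 in the fit, so the shares are not on the same footing. The 68.9% lies between the under 50% set for a wrong label and the 90% or more set for a right one. It leaves a wrong label and a mixed or partly different line open. KO line 3 is also Xist-high (19659 CPM), so an intact Fmr1 allele on a second X chromosome stays open as well and was not tested, and with one its values would not be those of a full knockout. The Fmr1 level of KO line 3 was 2.17 times the mean of KO lines 13 and 16, and 1.4 times with GC and length trends removed. That lies between the bounds of 1.2 and 1.5 set for this test, so a trend may account for part of the gap. The trend need not be that of KO line 3. Its rho with GC content was -0.092, against 0.258 in KO line 13 and 0.337 in KO line 16. With the trends removed the log2 fold change of Fmr1 was 0.066. Part of the lower level of KO lines 13 and 16 may thus be a trend too. An allele that disrupts the protein while the gene is still transcribed is a candidate explanation for the mean of the libraries labelled KO at 93% of WT, a mean that KO line 3 raises with 371 CPM beside 188 and 153 CPM in KO lines 13 and 16 and a mean of 256 CPM in WT, and counts per gene cannot tell it apart from an intact gene.

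The number of called genes was large. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called 5884 genes, and the highest of the others called 0, but 10 splits are too few for a share under 0.05. Every other split also mixed both genotypes in each group. A difference that follows the labels then counts as spread within groups, so few calls were to be had there and the 0 cannot measure chance. Removing GC and length trends left 121% of the main count (7152 genes) and an Xist covariate left 107% (6290 genes), which argues against either as the whole cause. Cytoplasmic RNA carried into the nuclear fractions of one genotype would move abundant cytoplasmic messages alike. In 3 of 3 libraries labelled KO the median of ribosomal protein genes lay above the WT mean (by 0.14 to 0.58 on the log2 scale) and that of oxidative phosphorylation genes below it (-0.20 to -0.68). Single WT libraries ran from -0.24 to 0.16 and from -0.26 to 0.20. KO lines 3 and 13 thus lay within the WT range for the first and KO line 16 for the second. Within each WT library, however, both medians lay close together. They were 0.16 and 0.20 in WT line 3, 0.09 and 0.06 in WT line 8, and -0.24 and -0.26 in WT line 19. They parted in KO line 3 (0.15 and -0.60), KO line 13 (0.14 and -0.68) and KO line 16 (0.58 and -0.20). Carry-over that moves cytoplasmic messages alike would not by itself part these lists. This test cannot tell whether it was present beside a separate fall of oxidative phosphorylation RNA. Both medians were higher in KO line 16 than in KO lines 3 and 13, and KO line 16 had the highest share of Actb (0.141% of counts). Actb, at 0.117% in the libraries labelled KO against 0.0736% in WT, goes with carry-over, which thus stays open. Genotype itself, and differences between independently derived lines that happen to follow genotype, such as region of origin or time in culture, stay open and were not tested.

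For the gene lists, 7 of the 10 splits, the real one included, had at least as many lists past camera at the preset correlation as the real 9, and the highest of the others had 17. The other splits mixed both genotypes in each group, and 10 splits are too few for a share under 0.05. Mixing did not keep lists from being called, since the split with 17 lists called 0 genes. The number of lists past camera at the preset correlation thus did not set the real grouping apart from the others. Sequence carried along with a targeted Fmr1 allele may change genes beside it: within 10 Mb of Fmr1, 35 of 72 genes were called (48.6%), against 161 of 407 on the rest of the X chromosome (39.6%). The odds ratio was 1.44 (95% interval 0.845 to 2.47, Fisher's exact test p = 0.155), so an excess could not be told from chance. In the list of neighbours fixed beforehand, 5 of 15 rose and 3 fell, with Hmgb3 at a log2 fold change of 1.97 and Mtm1 at -1.27.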
